A study of Enterococcus faecalis OG1RF with 4 samples.

How the data were processed

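Total RNA of 4 separate cultures of Enterococcus faecalis OG1RF was labelled with Cy3 and hybridised by the array maker to 1-colour NimbleGen arrays, per the labels. An array holds 72037 spots: 4839 spots of random sequence and 2 spots for each of 33599 probes of 3114 gene sequences of strain V583, with 11 probes for 3002 of the genes and fewer for the rest. The RNA is from OG1RF, so hybridisation crosses strains.

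The deposited raw files give the intensity of each spot on a linear scale, extracted with NimbleScan 2.4.31 per the file headers, with no background subtraction visible in the values. A further set of probe files deposited by the authors holds intensities on a linear scale that share a common distribution over the 4 arrays, and their name refers to the RMA method. Their software is not given in the sources used here. The authors' value table of the series holds linear intensities in 6228 rows, 2 for each gene. On each array its sorted log2 values correlated at over 0.99 with the sorted medians per gene and spot block of the second set. Its medians were 161 and 129 for the control arrays and 189 and 188 for the iron arrays. Its rows carry a number and no gene identifier, so it served only for counts of rows and for correlations. Its scale is linear and not centred. How it was summarised is not given in the sources used here.

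The raw intensities were background corrected with limma's normexp method and an offset of 50, taken to log2 and quantile normalized over the 4 arrays, random spots included. The spots of a probe were averaged and the probes of a gene summarised by median polish over the arrays. Work was done in R 4.3.3 with limma 3.58.1 and data.table version 1.17.8, and plots were drawn with matplotlib. A gene was above background on an array if its level exceeded the 95th percentile of the random spots. Where a gene was at background on both arrays of a group, its fold is a lower bound: the brighter group's mean over the mean of, per array, the higher of the background level and the gene's own level. Where it was at background on 1 of the 2 arrays, a fold written as a lower bound is computed the same way. No fold is given where that bound does not exceed no change. Saturated spots, 9 to 33 an array, were kept. The number of arrays limits the precision, with 2 per group and 2 residual degrees of freedom per gene, to which limma's eBayes added 2.29 prior degrees of freedom. Errors are SEs of the log2 difference from that fit.

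Iron was compared with control by limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all 3114 genes and no filter, at an adjusted p under 0.05. The replicate number was not used as a block. Of 20 function lists given by locus tags, 16 had at least 5 genes on the array and were tested with limma's camera at a preset correlation of 0.01, adjusted over the 16 lists, with an estimated correlation and fry as alternatives. A further 6 lists, for iron-sulfur enzymes, DNA repair, sugar phosphotransferase systems, amino acid and peptide transport, ribosomal proteins and tRNA synthetases, were defined by product names. The files used here hold none, so these lists were not formed. The 8 position lists of V583 regions held 412 genes on the array. Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined.

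The rule for named genes takes every member above background of the lists for iron uptake, metal regulators, iron storage and iron-sulfur assembly, which gave 15 genes. It also takes the 3 members with the smallest p of each other function list, which gave 48, for 63 in all. A further part, the largest changes among genes with a product name, gave none, since the files name no products. Members of the lists named beyond the rule, and EF0003, EF0820, EF1058 and EF2965, were chosen after their values were seen.

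The steps were tested on simulated arrays of 3114 genes for iron against control. Of 50 genes each, 28% with a true log2 change of 1, 32% with -1, 72% with 2 and 66% with -2 were called in their direction. All of these were drawn from the 1128 genes above background on all 4 arrays, so the rates do not cover dimmer genes. Of 2903 unchanged genes 2 were called, 1.96% of all calls. On the real arrays 7 of 412 genes of regions that OG1RF lacks were called, so the simulated share need not hold there. A list given a shift was called by camera and 0 other lists were. The simulated genes varied independently of each other, so this does not test camera's preset correlation on lists whose genes vary together. No difference in gene signal between scan sessions was simulated.

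The alternatives were other background corrections, normalizations and probe summaries, the authors' values, a filter on dim genes, the V583 regions left out, other variance models, a replicate block, each array left out in turn, fold thresholds, other set tests and, added after seeing the data, the removal of a trend with the span of a gene's probes. Scan dates in the file headers fall into 2 sessions, each with 1 group.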

Results

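Transcript levels were measured in Enterococcus faecalis OG1RF, a laboratory strain of a lactic acid bacterium, with and without an excess of iron. Wild-type cells were grown aerobically at 37 °C in N medium, a peptone, yeast extract and glucose broth, to mid-log phase. The iron cultures received 0.5 mM ferric nitrilotriacetate (Fe-NTA), a chelated iron salt, for 6 h before harvest. The control cultures received none, and no group received the chelator without iron, so iron and chelator cannot be told apart here. There were 4 separate cultures, 2 control and 2 iron, each hybridised to its own 1-colour array. The array carries probes for 3114 gene sequences of strain V583, a relative of OG1RF, so a gene of V583 that OG1RF lacks has no matching RNA. Genes are given by their V583 locus tags. The deposited files do not pair the tags with gene names, and the functions given here are those of lists drawn up from general knowledge of the V583 annotation, which were not checked against an annotation.

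The iron arrays showed more genes above background than the control arrays. The background level of an array was the 95th percentile of its 4839 random-sequence spots. Of the 3114 genes, 1387 and 1180 lay above it on control replicates 1 and 2, against 1663 and 1671 on iron replicates 1 and 2. The 75th percentile of the raw intensities was 747 and 539 units on the control arrays and 1232 and 1183 units on the iron arrays. Spots of the same probe correlated at 0.964 and 0.950 on the control arrays and at 0.986 and 0.984 on the iron arrays, so the control arrays were the less precise pair. Across genes, which are not independent replicates, normalized log2 levels correlated at r = 0.974 between the control arrays and r = 0.983 between the iron arrays, and at 0.884 to 0.897 between arrays of different groups. The SD of the log2 differences was 0.41 between the control arrays, 0.34 between the iron arrays and 0.83 to 0.87 across groups. Both control arrays were scanned in 1 session and both iron arrays in another, so scan session and group cannot be told apart in any comparison here.

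Genes of V583 elements that OG1RF lacks gave almost no signal. Of 412 genes in 8 such regions (the vanB vancomycin resistance element, the pathogenicity island and 6 prophages), 2 lay above background on all 4 arrays, or 0.485% with an exact 95% binomial interval of 0.0588% to 1.74%. Of 2576 other chromosomal genes, 43.6% did (interval 41.7% to 45.6%). Among 126 genes of the V583 plasmids, 2 were above background on all 4 arrays. By limma 0 of the 412 genes were called higher in iron and 7 lower at an adjusted p under 0.05, and 0 were higher and 29 lower at an unadjusted p under 0.05. Their median log2 change was -0.15. With the 99th percentile of the random spots as background, none of the 412 genes was above it on all arrays.

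The comparison of iron with control cultures addresses how the bacterium's transcripts respond to iron excess. Iron cultures had much lower levels of manganese transporter genes, of the arginine deiminase genes and of the iron-sulfur cluster assembly genes. They had higher levels of most pyrimidine synthesis genes, of several chaperone genes and of several genes of defence against oxidants. In all, 570 of 3114 genes differed by limma's moderated test at a Benjamini-Hochberg adjusted p under 0.05, with 351 higher and 219 lower in iron. The median log2 change was 1.24 among the higher genes and -1.45 among the lower ones, and 231 and 160 of them changed at least 2-fold. Without the adjustment 1012 genes had p under 0.05. Of the called genes, 121 of the higher ones were at background on both control arrays and 21 of the lower ones on both iron arrays, so that their change has only a lower bound, and 10 were at background on all arrays. Among the 560 called genes with signal, 485 had every probe moving in the gene's direction. The largest changes outside the lists were a rise of EF0003 by 3.88 (SE 0.44) on the log2 scale, a rise of EF0820 that was at least 8.67-fold, a fall of EF1058 that was at least 19.1-fold and a fall of EF2965 with a log2 change of -4.15 (SE 0.33), with limma adjusted p of 0.0132, 0.0086, 0.0059 and 0.0090. EF0003 has a short probe span, and genes of short span tended to be higher on the iron arrays.

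The count of calls rests on 2 arrays a group. It fell to 328 without control replicate 1, 289 without control replicate 2, 263 without iron replicate 1 and 270 without iron replicate 2, where the lone array of a group is taken to vary like the other group. Scaling the arrays to a common median in place of quantile normalization gave 762 higher and 133 lower genes, so that 85.1% of calls were higher, against 61.6% with quantile normalization and 51.7% with cyclic loess (252 higher and 235 lower). Without control replicate 1 the split was 163 higher and 165 lower, and without control replicate 2 it turned to 129 higher and 160 lower. Of the 63 genes named by the rule fixed in advance, 45 were called. Of these, 20 stayed called with any 1 array left out, and 25 did not stay called without at least 1 of the arrays. None of the 45 changed sign with an array left out. Under the other alternatives 24 of the 45 lost their call at least once, 15 with median scaling, 8 without background correction, and 6 each with cyclic loess and on the authors' probe values.

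**Figure D1:**
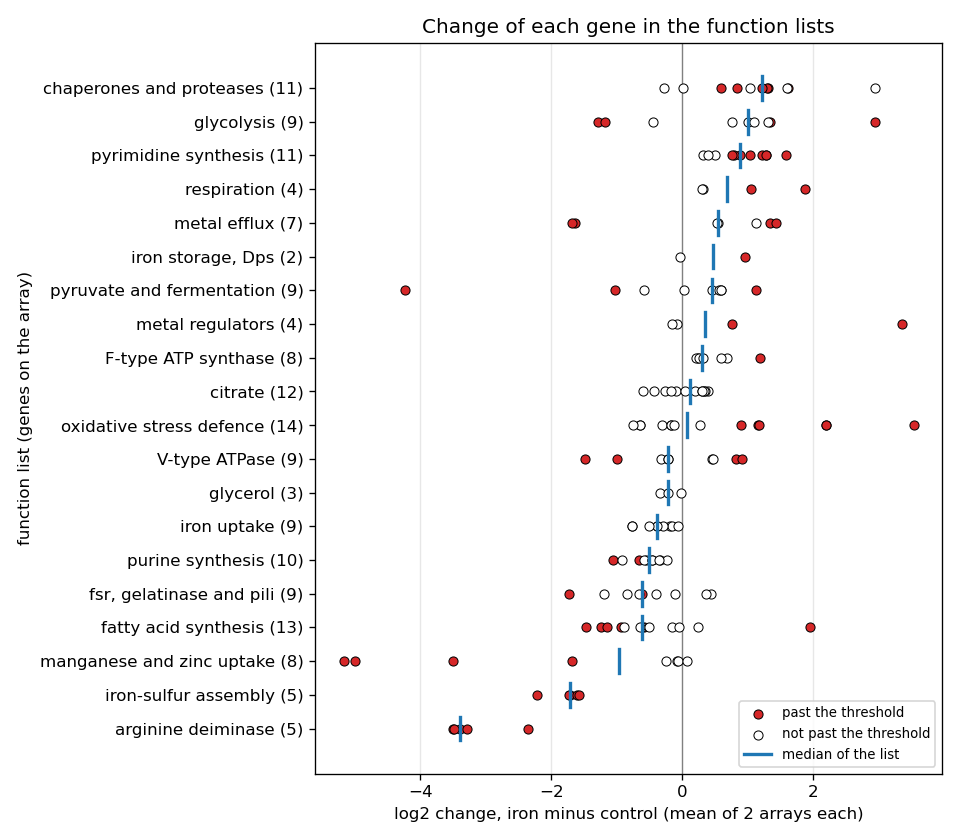
Log2 change (iron minus control, means of 2 arrays each) of every gene in the 20 function lists, 1 point a gene, filled where the adjusted p was under 0.05, with the list's median as a vertical bar and the number of genes in parentheses. The 5 genes of arginine deiminase and the 5 of iron-sulfur assembly all lie to the left of 0, and the 11 of pyrimidine synthesis to the right.

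The metal transporter genes EF2076 and EF1057 showed the largest falls of any listed genes, and none of the genes listed for iron uptake passed the test with the main settings. EF2076, EF2075 and EF2074 encode the substrate-binding protein and the other parts of a manganese ABC transporter, and EF1057 is an Nramp-type metal transporter. EF2076 fell by 5.17 (SE 0.19) on the log2 scale, and EF1057 fell too, with a limma adjusted p of 0.0059 for both. Each was above background on only 1 of the iron arrays, and with the other array at its background level the falls were at least 33.4-fold and 30.6-fold. EF2075 fell at least 8.82-fold, with both iron arrays at background, and EF2074 fell too, with a log2 change of at most -1.57 against the background level. The other 4 of the 8 genes listed for manganese and zinc uptake did not pass. Of these, EF0575, EF0576 and EF0577 lie in the listed pathogenicity island that OG1RF lacks, and were at background on all arrays. These 3 tags carry no result for OG1RF but still enter the list's median and tests. EF1901 had a log2 change of 0.07 (SE 0.23). The count was the same, 0 higher and 4 lower, adjusted over the list alone. By limma's camera the list was lower than other genes (adjusted p = 0.0031, median log2 change -0.97), but not with an estimated correlation between its genes, which gave an adjusted p of 0.434.

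The 9 genes listed for iron uptake had changes between -0.77 and -0.07 with a median of -0.38, and 0 passed by limma over all genes and 0 adjusted over the list alone, while 3 were lower at an unadjusted p under 0.05. The camera adjusted p was 0.052, and 0.555 with an estimated correlation. The largest change was that of EF0476, listed as a ferrous iron transporter, at -0.77 (SE 0.19, limma adjusted p = 0.064). EF0476 was called lower in 4 of 18 alternatives, with the mean over probes (-0.88), a normexp offset of 0 (-0.95), an intensity trend in eBayes (-0.77) and on the authors' probe values, where its change was -1.81. Its adjusted p ran from 0.026 to 0.235 over the alternatives. Genes listed for iron-compound ABC transporters gave -0.77 (SE 0.27, and -1.72 to -0.40 over the alternatives) for EF3083, -0.51 (SE 0.24) for EF3084, -0.38 (SE 0.42) for EF0191, -0.18 (SE 0.39) for EF0192 and -0.16 (SE 0.19) for EF0193. These genes lay near background: 6 of the 9 exceeded it on any array, and the median change of the genes of absent regions, all but 2 at background on some array, was -0.15. The list passed camera's threshold in 10 of 17 alternatives, among them without control replicate 2 (adjusted p = 0.0016) and without iron replicate 2 (0.046).

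Among metal-responsive regulators, EF1585, a PerR-type peroxide sensor, rose while EF1525, a Fur-type regulator, showed no detectable change. EF1585 rose by 3.36 (SE 0.40) on the log2 scale, from a mean of 8.49 ± 0.63 (SD, n = 2) to 11.84 ± 0.46 (SD, n = 2), with a limma adjusted p of 0.0143. One control array was at background, and with it at its background level the rise was at least 9.50-fold. EF1525 had a log2 change of -0.15 (SE 0.16, limma adjusted p = 0.560), a value that turned positive in 2 alternatives. EF2417, a Zur-type zinc regulator, was called higher (limma adjusted p = 0.047), but its control signal was at background, its iron signal did not exceed the control background level, and the call was lost without any 1 of the arrays (adjusted p of 0.074 to 0.185). EF0578 was at background on all arrays and lies in the listed pathogenicity island that OG1RF lacks, so it carries no result for OG1RF. Adjusted over the list alone, 2 of the 4 regulators were higher, EF1585 and EF2417. Of the 2 genes listed as Dps-like or ferritin-type iron storage proteins, EF3233 rose 1.96-fold (log2 change 0.97, SE 0.12, limma adjusted p = 0.0146) and EF0606 was at background. EF0606 lies in the same missing island and carries no result either. Adjusted over the list alone the count was also 1 of 2. Without iron replicate 1 or iron replicate 2 the adjusted p of EF3233 was 0.079 and 0.068. Its call was also lost with cyclic loess (0.52, adjusted p = 0.115) and on the authors' probe values (0.59, adjusted p = 0.139), where the change was smaller. These lists were too short for camera.

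All 5 genes of iron-sulfur cluster assembly, EF2390 to EF2394, fell. Their products build the iron-sulfur cofactors of enzymes. The log2 changes ran from -2.22 (SE 0.23) for EF2393 to -1.58 (SE 0.19) for EF2394, with -1.71 (SE 0.16) for EF2390, -1.73 (SE 0.17) for EF2391 and -1.61 (SE 0.12) for EF2392, and limma adjusted p of 0.0086 to 0.0148. All 5 were above background on all 4 arrays, and all 5 also passed adjusted over the list alone. The camera adjusted p was 0.000126, and 0.344 with an estimated correlation. With median scaling the changes were smaller, with a list median of -0.65, and EF2391 and EF2392 no longer passed (adjusted p of 0.181 and 0.0917). EF2394 did not pass without iron replicate 1 or iron replicate 2 (adjusted p of 0.055 and 0.051).

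**Figure D2:**
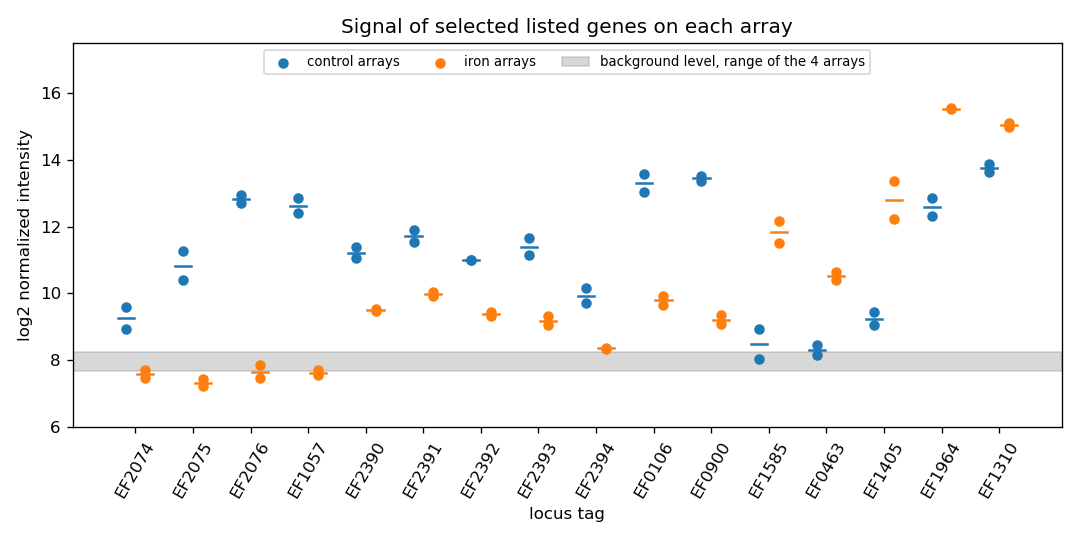
Normalized log2 intensity of 16 listed genes on each array, with control arrays in blue, iron arrays in orange, the group mean of 2 arrays as a short bar, and the range of the 4 background levels in grey. EF2076 and EF1057 lie at means of 12.8 and 12.6 in control and within or next to the background band in iron, while EF1585 rises from 8.49 to 11.84.

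Of 14 genes listed for defence against oxidants 6 rose, and the list as a whole did not pass camera with the main settings. EF1405, a thioredoxin, rose by 3.54 (SE 0.43) on the log2 scale, 11.6-fold. EF0453, of the organic hydroperoxide resistance family, rose by 2.21 (SE 0.39), and EF0463, the manganese superoxide dismutase, rose by 2.20 (SE 0.17). EF3270, a glutathione reductase, rose by 1.18 (SE 0.14), EF1681, a methionine sulfoxide reductase, by 1.17 (SE 0.16) and EF1338, a thioredoxin reductase, by 0.89 (SE 0.13). EF0463 and EF1338 were at background on 1 of the control arrays, and with it at its background level they rose at least 4.45-fold and 1.76-fold. The limma adjusted p was 0.0145 for EF1405, 0.0090 for EF0463 and 0.0135 for EF3270. The other 8 of the 14 listed genes did not pass, and all of them but EF1597 had changes below 0. Among these were -0.64 (SE 0.34) for EF1211, the NADH peroxidase, -0.65 (SE 0.41) for EF2739 and -0.30 (SE 0.52) for EF2738. EF2932 had a change of -0.75 (SE 0.24, limma unadjusted p = 0.032). EF1597, the catalase, was at background on 3 of the arrays. Adjusted over the list alone, the same count of 6 was higher and 0 lower. The list's median change was 0.07, with a camera adjusted p of 0.096 and of 0.434 with an estimated correlation. The list passed camera with median scaling, with a median of 0.78 and an adjusted p of 0.0072, and its fry adjusted p was 0.0125. EF1405 did not pass without control replicate 1 or control replicate 2 (adjusted p of 0.052 and 0.062), and EF3270 passed only without iron replicate 2 among the fits with 1 array left out, with adjusted p of 0.051, 0.050 and 0.057 in the others. With the median over probes EF3270 had a change of 0.62 and did not pass (adjusted p = 0.083).

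Of 11 chaperone and protease genes, 6 rose and none fell over all genes, and 9 rose adjusted over the list alone. The list's median change was 1.22, with a camera adjusted p of 0.0014, and of 0.344 with an estimated correlation. EF1306, EF1308 and EF1310, of the hrcA and dnaK operon, had log2 changes of 1.61 (SE 0.29), 0.84 (SE 0.16) and 1.30 (SE 0.14), with limma adjusted p of 0.033, 0.035 and 0.013. The GroES and GroEL genes EF2634 and EF2633 rose by 1.22 (SE 0.25) and 0.59 (SE 0.12). EF0771, the ClpP protease subunit, had a log2 change of 2.95 with an SE of 0.67 and did not pass over all genes. Calls in this list depended on single arrays and on the processing. With 1 array left out EF1306 kept its call only without iron replicate 2, EF1308 only without control replicate 1, and EF1310 had an adjusted p of 0.053 without iron replicate 2. EF1306 also lost its call with no background correction (adjusted p = 0.073) and with cyclic loess (0.052), EF1308 with cyclic loess (0.115), the median over probes (0.056), the replicate block (0.069) and on the authors' probe values (0.138), and EF1310 on the authors' probe values (0.052).

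All 5 arginine deiminase genes, EF0104 to EF0108, fell strongly. This pathway yields ATP and ammonia from arginine. EF0106, EF0108 and EF0105 had log2 changes of -3.51 (SE 0.23), -3.49 (SE 0.28) and -3.40 (SE 0.33), falls of 11.4-fold, 11.3-fold and 10.5-fold, with limma adjusted p of 0.0086, 0.0090 and 0.0110. EF0104 and EF0107 had changes of -2.35 (SE 0.35) and -3.28 (SE 0.32). All 5 also passed adjusted over the list alone. The camera adjusted p was 0.000126, and 0.434 with an estimated correlation. The 3 genes with the smallest p, EF0105, EF0106 and EF0108, kept their calls in all 18 alternatives.

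Among nucleotide synthesis genes, most of the pyrimidine list rose, while 2 genes of the purine list fell. The difference between the lists was not tested. In the pyrimidine list 8 of 11 genes rose and none fell, and 9 rose adjusted over the list alone. EF1721, listed as the operon's regulator and at background on 1 of the control arrays, rose by 1.59 (SE 0.20) and EF1718 by 1.29 (SE 0.12) on the log2 scale, and EF1712 rose at least 1.99-fold from a control signal at background, with limma adjusted p of 0.0158, 0.0105 and 0.0109. With its dim control array at the background level, EF1721 rose at least 2.75-fold. Over the 11 genes the median change was 0.88, with a camera adjusted p of 2.3e-05, and of 0.344 with an estimated correlation. Without control replicate 1 or control replicate 2 the adjusted p of EF1721 was 0.054 and 0.065. In the purine list 2 of 10 genes fell, 4 adjusted over the list alone. EF1784 had a log2 change of -1.06 (SE 0.18), EF1783 of -0.66 (SE 0.14) and EF1778 of -0.92 (SE 0.24), and EF1778 did not pass (limma adjusted p = 0.072). Tested only among genes above background on both arrays of a group, EF1778 passed (limma adjusted p = 0.044). The purine list's median change of -0.51 (camera adjusted p = 0.0057, and 0.543 with an estimated correlation) turned to 0.59 with median scaling, where the list did not pass (camera adjusted p = 0.065) and EF1783, EF1784 and EF1778 turned positive too. The purine list's fry adjusted p was 0.086. EF1783 lost its call without any 1 of the arrays (adjusted p of 0.081 to 0.219) and in all but 6 of the 18 alternatives, and with 1 array left out EF1784 kept its call only without control replicate 1.

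Genes of energy metabolism split. EF0900, the aldehyde-alcohol dehydrogenase of ethanol fermentation, fell by 4.23 (SE 0.15) on the log2 scale, 18.8-fold (limma adjusted p = 0.0059), from a mean of 13.45 ± 0.11 (SD, n = 2) to 9.22 ± 0.18 (SD, n = 2). In the same list of pyruvate and fermentation genes EF0641 was called lower and EF1353, of the pyruvate dehydrogenase complex, higher, so that 1 of 9 genes rose and 2 fell, both over all genes and adjusted over the list alone. EF0641 had a log2 change of -1.03 (SE 0.21), near 0 with median scaling, and EF1353 of 1.14 (SE 0.22). EF1353 lost its call without any 1 of the arrays (adjusted p of 0.052 to 0.121), with cyclic loess and without background correction (both 0.072), and with 1 array left out EF0641 kept it only without control replicate 1. The list's median was 0.46 while its mean was -0.27, and camera gave the direction higher with an adjusted p of 0.837 (0.906 with an estimated correlation). In glycolysis 2 of 9 genes rose and 2 fell, and 4 rose and 2 fell adjusted over the list alone. EF1964, a glyceraldehyde-3-phosphate dehydrogenase, rose by 2.95 (SE 0.22), 7.71-fold, with a limma adjusted p of 0.0086. On iron replicates 1 and 2, 2 and 1 of its 22 spots were saturated. EF1045, the phosphofructokinase, had a log2 change of -1.29 (SE 0.11) and EF1046, the pyruvate kinase, of -1.17 (SE 0.17), but neither passed with median scaling, where their changes were -0.17 and -0.02. EF1046 also lost its call without iron replicate 1 or iron replicate 2 (adjusted p of 0.086 and 0.068). The glycolysis list had a median of 1.00 and a camera adjusted p of 0.286 (0.555 with an estimated correlation), and passed only with median scaling (0.0095).

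Among the ATPases and the respiratory genes changes were mostly small with the main settings, but the list medians of the ATPases depended on the processing. Over the alternatives the F-type median ran from 0.23 to 1.30 and the V-type median from -0.47 to 1.02. In the F-type ATP synthase list 1 of 8 genes rose, 3 adjusted over the list alone. EF2614 had a log2 change of 1.19 (SE 0.17, limma adjusted p = 0.018), and EF2607 and EF2613 had changes of 0.68 (SE 0.17) and 0.59 (SE 0.14) that did not pass, but were 1.59 and 1.51 and did with median scaling. The list's median was 0.31, with a camera adjusted p of 0.0077 and of 0.384 with an estimated correlation. The list did not pass camera among genes above background on both arrays of a group (adjusted p = 0.223) or on the authors' probe values (0.101). With 1 array left out EF2614 kept its call only without iron replicate 2. In the V-type ATPase list 2 of 9 genes rose and 2 fell, both over all genes and adjusted over the list alone. EF1493 had a log2 change of -1.48 (SE 0.15) and EF1500 of 0.91 (SE 0.12), and EF1494 was lower 2.001-fold. The calls of EF1493 and EF1494 were lost with median scaling, and those of EF1494 and EF1500 without any 1 of the arrays (adjusted p of 0.050 to 0.094). With the median over probes EF1500 had a change of 0.40 and did not pass (adjusted p = 0.212). The list's median of -0.22 and mean of -0.07 differed in sign from camera's direction, which was higher at an adjusted p of 0.837 (0.934 with an estimated correlation), and the median turned positive with median scaling and without control replicate 1, control replicate 2 or iron replicate 1. Of 4 respiratory genes, EF2058 and EF2059 rose, by 1.88 (SE 0.25) and 1.06 (SE 0.16), and EF2060 had a change of 0.32 (SE 0.13) that did not pass. The count adjusted over the list alone was the same, 2 of 4. Without iron replicate 2 the adjusted p of EF2058 was 0.058, and with 1 array left out EF2059 kept its call only without control replicate 1. EF2059 also lost it with cyclic loess (0.69, adjusted p = 0.075) and on the authors' probe values (0.68, adjusted p = 0.109).

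Metal efflux genes changed in both directions, with 2 of 7 higher and 2 lower, or 3 higher and 2 lower adjusted over the list alone. EF2623 rose by 1.44 (SE 0.15) and EF0859 by 1.35 (SE 0.17) on the log2 scale, with limma adjusted p of 0.0116 and 0.0148. EF0859 was at background on 1 of the control arrays, and with it at its background level the rise was at least 2.18-fold. EF0758 had a log2 change of -1.64 (SE 0.23) and EF1400 of -1.68 (SE 0.26), and EF0758 did not pass with median scaling (-0.54) or without iron replicate 1 (adjusted p = 0.066). EF0859 did not pass without iron replicate 1 or iron replicate 2 (adjusted p of 0.053 and 0.060). The list's median was 0.56, or 0.13 with genes at background set to their bound, and camera gave an adjusted p of 0.216 (0.555 with an estimated correlation).

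Of 13 fatty acid synthesis genes 5 fell, 1 rose and 7 did not pass, and 9 fell and 1 rose adjusted over the list alone. EF2881 had a log2 change of -1.47 (SE 0.24), EF2879 of -1.25 (SE 0.13) and EF2880 of -1.15 (SE 0.14), with limma adjusted p of 0.026, 0.012 and 0.014. EF2874, the gene that rose, had a change of 1.96 (SE 0.33) and was at background on 1 of the control arrays. With that array at its background level the rise was at least 3.08-fold. The median of -0.62 (camera adjusted p = 0.0057, and 0.555 with an estimated correlation) turned to 0.09 with median scaling, where EF2879, EF2880 and EF2881 lost their calls. The list's fry adjusted p was 0.086. EF2881 also lost its call with the replicate block (limma adjusted p = 0.056) and with no background correction (0.052). Without iron replicate 1 the adjusted p of EF2880 was 0.064 and that of EF2881 0.093, and without iron replicate 2 that of EF2879 was 0.051 and that of EF2881 0.065.

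The lists of surface and secreted virulence factors, citrate and glycerol metabolism showed little change past the threshold. In the first, which holds the fsr regulators, gelatinase and pilus genes, 2 of 9 genes were called lower, both over all genes and adjusted over the list alone. EF1091, a pilus tip protein, had a log2 change of -1.73 (SE 0.17, limma adjusted p = 0.0110), and EF1094 a change of -0.62 (SE 0.14) whose call was lost without any 1 of the arrays (adjusted p of 0.073 to 0.227). EF1091 did not pass with median scaling (adjusted p = 0.054). EF1818, the gelatinase, and EF1817 had changes of -0.84 (SE 0.32) and -0.39 (SE 0.12) that did not pass. EF1817 was called lower in 2 of 18 alternatives, with cyclic loess, where its change was -0.86 (adjusted p = 0.049), and without background correction (0.049), and its adjusted p ran up to 0.503. It was among the brightest genes, with a mean of 15.89 in control, and up to 4 of its 22 spots on an array were saturated. The list had a median of -0.62 and a camera adjusted p of 0.064, and of 0.555 with an estimated correlation. It passed camera's threshold in 6 of 18 alternatives, among them without control replicate 1 (0.027) and without iron replicate 1 (0.035). By limma 0 of the 12 citrate genes and 0 of the 3 glycerol genes passed over all genes, adjusted over the list alone or at an unadjusted p under 0.05. Citrate genes had a median change of 0.12 (camera adjusted p = 0.733, and 0.906 with an estimated correlation), with -0.43 (SE 0.19) for EF3318. EF3325 was at background on both control arrays, and its iron signal did not exceed the control background level. The glycerol genes EF1927, EF1928 and EF1929 had log2 changes of -0.01 (SE 0.17), -0.33 (SE 0.18) and -0.22 (SE 0.16), which all turned positive with median scaling.

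No list that camera called with the preset correlation of 0.01 was called with an estimated correlation, where 0 of 16 passed and 1 had an unadjusted p under 0.05. The estimates come from 4 arrays and have 2 residual degrees of freedom, and camera then tests on these 2 as well. With so few, the loss of a call cannot be put down to correlation between genes. The pyrimidine, chaperone and F-type ATP synthase lists had estimates of -0.064, -0.060 and -0.011, under the preset 0.01, and lost their calls too. The other lists that camera called had estimates of 0.083 to 0.85. By fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, 8 lists passed, of which 6 were among the 8 called by camera. The others were those of defence against oxidants and of pyruvate and fermentation.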

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

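The removal of the span trend was the only alternative chosen after seeing the data. Of 1131 values of named genes under an alternative, 977 kept direction and side of the threshold, 120 lost and 12 gained a call in the same direction and 22 changed sign, of which 4 also lost a call. Of 287 list values 258 kept both, 2 lost (both of the F-type ATP synthase list) and 18 gained a call in the same direction and 9 changed sign, of which 2 also lost a call (the purine and fatty acid lists with median scaling). The cause of a change was not tested, except that fewer arrays or a stricter threshold leave less to pass by construction. The list and named-gene results were not run on the authors' gene values, whose rows name no gene. There 1224 of 6228 rows passed (19.7%, against 18.3% of genes here). Signal near background limits the dim genes.

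The count of 570 called genes (351 higher, 219 lower) stayed within 1.5 times under the other alternatives, except these. Without background correction 232 were higher. With median scaling 895 were called, 762 higher and 133 lower, and 30 of the 570 genes had the other sign. With a 2-fold minimum 231 were higher. With 1 array left out 263 to 328 were called, 129 to 169 higher and 101 to 165 lower, with 237 to 271 of the 570 kept. The replicate block gave 436 genes, 264 higher and 172 lower, with 393 of the 570 kept, and 8 lists. Same-numbered arrays deviated from their group means with a correlation of 0.037 across genes. This shows no large effect shared by same-numbered arrays, but cannot tell whether their cultures were handled together. With the span trend removed 606 were called.

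Camera called 8 lists with the preset correlation and 7 to 10 under the other alternatives of the values. It called 0 with an estimated correlation, and fry called 8 by direction and 15 for change in either direction. The absent regions had 0% of genes above background with the 99th percentile. Replicate r was 0.969 (control) on raw log2 values, and 0.965 (control) and 0.986 (iron) on the authors' gene values.

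With median scaling the median change of the V-type ATPase list turned to 1.02, of the purine list to 0.59 and of the fatty acid list to 0.093. The change of EF0192 turned to 0.24, of EF0193 to 0.0032, of EF0641 to 0.00068, of EF1525 to 0.24, of EF1778 to 0.10, of EF1783 to 0.53, of EF1784 to 0.14, of EF1927 to 0.54, of EF1928 to 0.33, of EF1929 to 0.48, of EF2880 to 0.012 and of EF3318 to 0.43. With cyclic loess the citrate list turned to -0.026 and EF2060 to -0.12. With the median over probes the citrate list turned to -0.024 and EF1927 to 0.035. EF1927 was 0.0055 with a normexp offset of 0 and 0.015 on the authors' probe values. With 1 array left out the V-type ATPase list lay between -0.47 and 0.28, the citrate list between -0.041 and 0.22, EF0191 between -0.97 and 0.21, EF0192 between -0.70 and 0.34, EF0193 between -0.32 and 0.0015, EF1525 between -0.31 and 0.0073 and EF1927 between -0.17 and 0.15.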

Other observations

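Cyclic loess was chosen in advance as a normalization and set against an explanation only after its result was seen, and the other tests given here, the removal of the trend with gene span among them, were chosen after seeing the data, as were both lists described here. The tags EF1276 to EF1293, which general knowledge of V583 places in its prophage 2, fell together in iron. All 17 on the array were called lower by limma, with log2 changes from -3.75 to -1.12 and a median of -2.73. They were among the brightest genes of the control arrays, with a median log2 level of 14.20 against 8.09 for other chromosomal genes, and in iron their median of 10.96 still lay above the 8.25 of the others. All 17 were above background on both iron arrays. With median scaling 15 of the 17 were called lower, with a median of -1.89.

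Ribosomal protein genes of the cluster EF0205 to EF0226 were mostly not past the threshold. Of 21 on the array 2 rose, EF0205 and EF0206, with log2 changes of 2.19 (SE 0.25) and 2.18 (SE 0.33), and the median was 0.68. In many of the other members the iron arrays lay far apart, with iron replicate 1 below control replicate 1. EF0215 had levels of 13.55 and 12.97 on control replicates 1 and 2, and of 12.49 and 14.16 on iron replicates 1 and 2. The median above 0 therefore rests largely on iron replicate 2. With median scaling 8 rose and the median was 1.71. These genes have short probe spans, with a median highest position number of 291, and with the span trend removed the median was 0.56. Called genes also lay side by side on the chromosome: 28 runs of at least 4 neighbouring tags were called in the same direction, 19 higher and 9 lower, and held 135 genes. In 10000 shuffles of the calls along the tags the median was 0 runs and the highest was 5, a permutation p of 1e-04, the smallest they can give. The shuffles treat all tags as exchangeable, including those of regions that OG1RF lacks and those that share an operon. Their p therefore bears neither on iron nor on the quality of the calls.

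The 570 called genes were weighed against a difference between arrays that has nothing to do with iron. There are only 3 ways to part 4 arrays into 2 and 2, too few for a share under 0.05. The real split gave 570 genes, each of the others gave 0, and 1 of the 3 splits gave as many. Cyclic loess, which removes a signal difference between scan sessions that depends on brightness alone, left 79.6% of the 570 genes called in their direction. The main fit's quantile normalization already gave the 4 arrays a common distribution of brightness, so this result cannot decide on that explanation. A trend with gene span is argued against by its removal, which left 91.4%. Differences between scan sessions cannot be told apart from iron, since 0 sessions hold both groups, and the effect of iron itself stays open with them.

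Genes with a short probe span were higher on the iron arrays. The span is the highest number at the end of a gene's probe IDs, taken to count bases from the gene's start, which the files do not state. Over 1128 genes above background on all arrays the median log2 change went from 0.31 in the 226 genes with the shortest span to -0.23 in the 226 with the longest, and the correlation across genes was -0.14 (Spearman). Within a gene, the probes in the first 20% of ranks, by the position number in their IDs, had a log2 change 0.133 (SE 0.020) higher than those in the last 20%. This is a shift of 6.65 standard errors over 1111 genes. That error is a spread over genes, which are not independent replicates, and does not measure the spread between arrays. If the numbers follow the gene, RNA fragmentation or labelling that differs between arrays could give such a shift. Changes of whole transcripts cannot be told apart from it as a further part of the trend, since both control arrays (0.11 and 0.14) and both iron arrays (-0.19 and -0.05) shared a sign and a shift within genes does not exclude them.

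For the fall of EF1276 to EF1293, a trend with gene span is argued against as the whole cause: its part in the change was above 0, the opposite of a fall, in 11 of the 17 tags, and it made up at most 9.71% of the fall of any tag. Residual chromosomal DNA in the control samples would raise all chromosomal genes to about the same level, and is argued against because 98.9% of other chromosomal genes lay below the tags' median control level. Extra copies of this region alone were not tested. A difference between scan sessions cannot be told apart from iron, with 0 sessions that hold both groups. Lower transcription of this region in iron is a hypothesis only, and another culture series scanned in mixed order would test it.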
